A study of Mus musculus with 4 samples.

How the data were processed

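RNA from cells labelled as magnetically enriched primordial germ cells of C57BL/6 embryos at E12.5 was measured in 4 libraries of 1000 cells each, made with a modified Smart-seq2 protocol and Tn5 transposase, per the labels' protocols. The marker used for the enrichment is not given in the sources used here. The deposited values are whole-number counts per gene in 1 table, with 1 column per library. Per the submitters' processing notes, Trim Galore, FastQC, HISAT2, SAMtools and featureCounts were used with the mouse build mm10. Per the file headers, the counts were made with featureCounts 1.6.2 on the GENCODE M17 gene set. Per the file headers, read pairs were counted as fragments with a mapping quality of at least 30. The option to count reads with several alignments was set, but it takes in only those that reach this quality. Reads overlapping several genes were counted for each of them, and no strand option was set. Counts of overlapping genes, of antisense partners and of near-identical copies such as the alpha-globins are therefore uncertain, and genes with close pseudogenes can be undercounted by the mapping quality limit. No normalization had been applied to the deposited counts.

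Groups came from the genotype label and replicate numbers from the sample titles. The table holds 53715 genes, and gene symbols were looked up by Ensembl identifier; 95 identifiers had no symbol and kept their identifier. Coordinates are those of the table, on mm10, from the first exon start to the last exon end. All 4 columns of counts were used. Replicates were compared before averaging: the chi-square per degree of freedom between the counts of the pair was 124 for WT and 105 for Rif1_KO, so the libraries of a pair differ by more than sampling noise.

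Genes were kept with edgeR's filterByExpr by group (minimum count 10), which left 15466 genes. The main test was edgeR's quasi-likelihood test (edgeR 4.0.16 in R 4.3.3, robust dispersion, TMM factors of 0.856 and 0.8 for WT and 1.107 and 1.319 for Rif1_KO), with Benjamini-Hochberg adjustment at 0.05 and no covariate. Fold changes are Rif1_KO against WT on the log2 scale, and SE is the log2 fold change divided by the square root of the F statistic. The common biological coefficient of variation was 0.84. The median log2 fold change of all tested genes was -0.111 with TMM, -0.195 with DESeq2 size factors and 0.164 with upper-quartile factors, and single fold changes are to be read relative to that. Levels are CPM, counts per 1000000 of the TMM-scaled library total, while shares of counts and floors use the total as deposited, the floor being 3 counts.

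A set of 29 gene lists with 828 entries was fixed before the data were examined: pluripotency and early germ cell regulators, gonadal germ cell, meiotic, male and female germ cell fate and two-cell stage genes, DNA methylation, H3K9 and H3K27 methylation, replication, break repair, p53 target, mitotic, apoptosis, interferon, imprinted, BMP, WNT, glycolysis, oxidative phosphorylation, ribosomal protein and dissociation stress genes, markers of supporting, stromal, endothelial, erythroid, leukocyte and mesonephric cells, Y-linked genes and Xist. Of the entries 10 matched no gene of the table. Lists with at least 5 tested members and the set of X-linked genes were tested on log2 CPM with camera (limma 3.58.1, inter-gene correlation 0.01, two-sided), with adjustment over these sets. The number of members that pass adjusted over the list alone was also counted. Haemoglobin genes, the rRNA-region genes of chromosome 17 and a list of oocyte and egg genes were collected after the values had been seen.

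The genes named in the text follow a rule fixed before the data were examined. Rif1 comes first, then the 10 genes with the smallest p in each direction among those with an adjusted p under 0.05, non-overlapping CPM values, a mean of at least 5 CPM in the higher group and an assigned name. All that pass are named where fewer do, and the 5 with the smallest unadjusted p are given as values where none does. For each list up to 4 members past the threshold are named, otherwise up to 2 with the smallest p, and Xist and every detected Y-linked gene are named. Of the genes the rule takes, 1 is not reported here. Genes outside the rule are marked in the text as chosen after their values were seen.

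The steps were tested on simulated counts with the means, library sizes and dispersion of these libraries. Of genes changed 4-fold, 16-fold and 64-fold among 15466 simulated genes for Rif1_KO against WT, edgeR recovered 4.48%, 41.8% and 81.8% with 0 false calls. DESeq2 recovered 4.48%, 62.7% and 98.5% with 133 false calls, and limma-voom 1.49%, 5.97% and 33.3% with 0 false calls. A simulated list of 20 genes changed 4-fold had a camera adjusted p of 1.98e-07, and 0 of 26 unchanged lists were called. The simulated genes were drawn independently of each other, so this gives no false call rate for lists whose genes vary together. By the recovery rates, changes of 4-fold were mostly out of reach of the main test at this spread. The changed genes were drawn only from genes with higher counts, and each gene had the same dispersion under both labels. The rates therefore do not cover genes with low counts, or the larger spread between the libraries labelled WT.

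The alternatives were DESeq2 1.42.0, limma-voom, DESeq2 size factors or upper-quartile factors in edgeR, no filter on low counts, a stricter filter of 5 CPM in at least 2 libraries, a replicate block, glmTreat against a log2 fold change of 1, a fit without robust dispersion, each library left out in turn, and a fit without genes of the X and Y chromosomes. For the lists, camera with an estimated correlation and fry were run, and for library shares a total without mitochondrial genes. A fit without haemoglobin, mitochondrial and rRNA-region genes was added after seeing the data.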

Results

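The data were RNA-seq counts from cells that the labels call primordial germ cells, the precursors of eggs and sperm, collected from C57BL/6 mouse embryos at E12.5. The comparison was of libraries labelled as Rif1 knockout with libraries labelled as wild type. Rif1 encodes a chromatin-associated protein that acts in replication timing and in the choice of repair pathway at DNA breaks. The cells were enriched with magnetic beads, and 1000 cells went into each Smart-seq2 library, a full-length cDNA method for small samples. There were 2 libraries labelled WT and 2 labelled Rif1_KO, and no label says whether the libraries of a group came from separate embryos. The p-values of single genes therefore measure the spread between these libraries, which may be technical. Those of the list test camera at its preset correlation compare a list with the other genes. They rest on the spread across genes, not on the spread between libraries. The purity of the sorted cells is not given in the sources used here and is in doubt, since germ cell markers were low in most libraries and haemoglobin transcripts were abundant under the label WT, as given below by library. Totals were 12768932 and 11724630 counts in the libraries labelled WT (replicate 1, then 2, here and in every pair of values), and 12071903 and 14421298 in those labelled Rif1_KO. Genes with 10 counts or more numbered 13314 and 13566 in the libraries labelled WT, and 15226 and 16211 in those labelled Rif1_KO.

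Rif1 itself (ENSMUSG00000036202.16, chromosome 2, 52072832 to 52122383, mm10) was read first, as a check of the labels. Its level was 43.7 and 4.73 CPM (counts per 1000000, TMM-normalized) in the libraries labelled WT, from 474 and 44 counts. It was 86.2 and 63.9 CPM in the libraries labelled Rif1_KO, from 1144 and 1207 counts. The group means were 24.2 ± 27.5 CPM and 75.1 ± 15.7 CPM (SD, n = 2 each). Rif1 transcript was therefore higher, not lower, in both libraries labelled Rif1_KO, and the count of this gene goes against the labels. For this reason libraries are named by their label throughout, and each direction given here is that of the labels. The log2 fold change was 1.63 (SE 1.01) and was not called by edgeR's quasi-likelihood test, with an adjusted p of 0.717. The log2 fold change was 3.99 without WT replicate 1, 0.78 without WT replicate 2, 1.47 without Rif1_KO replicate 1 and 1.83 without Rif1_KO replicate 2. The labels do not say which part of the gene was deleted, and 1 count per gene cannot tell reads of the remaining exons from reads of an intact transcript.

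Transcripts of red blood cells were far lower in the libraries labelled Rif1_KO. Haemoglobin genes took 11.8% (95% Clopper-Pearson interval 11.7 to 11.8) and 8.92% (8.90 to 8.94) of all counts in the libraries labelled WT. They took 1.09% (1.08 to 1.09) and 0.555% (0.552 to 0.559) in those labelled Rif1_KO, as the plot of library composition shows. The means were 10.3% ± 2.01 and 0.82% ± 0.374 (SD, n = 2 each), a ratio of 12.6. Overlapping gene models of an rRNA repeat region on chromosome 17 (Gm42418, AY036118 and CT010467.1) took 15.8% and 17.6% of counts under the label WT, and 3.87% and 7.15% under the label Rif1_KO, a ratio of the means of 3.03. Because reads were counted once for every gene they overlap, these 3 models hold the same reads in part. Mitochondrial genes did not separate the labels, with 14.2% and 20.1% in the libraries labelled WT and 21.0% and 14.5% in those labelled Rif1_KO. Cytosolic ribosomal protein genes took 3.16% and 2.78% under the label WT and 4.32% and 3.98% under the label Rif1_KO. This order of the labels is one of raw shares only, since the TMM-normalized sums of these genes were 37120 and 35070 CPM against 39250 and 30400 CPM. The 50 genes with the most counts in a library held 49.8% and 53.9% of counts under the label WT, and 38.5% and 33.0% under the label Rif1_KO. With 2 libraries against 2, an exact two-sided permutation test cannot give a p below 0.333, so these shares were not tested. The intervals cover counting error only, since the reads carry no molecular identifiers.

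**Figure D1:**
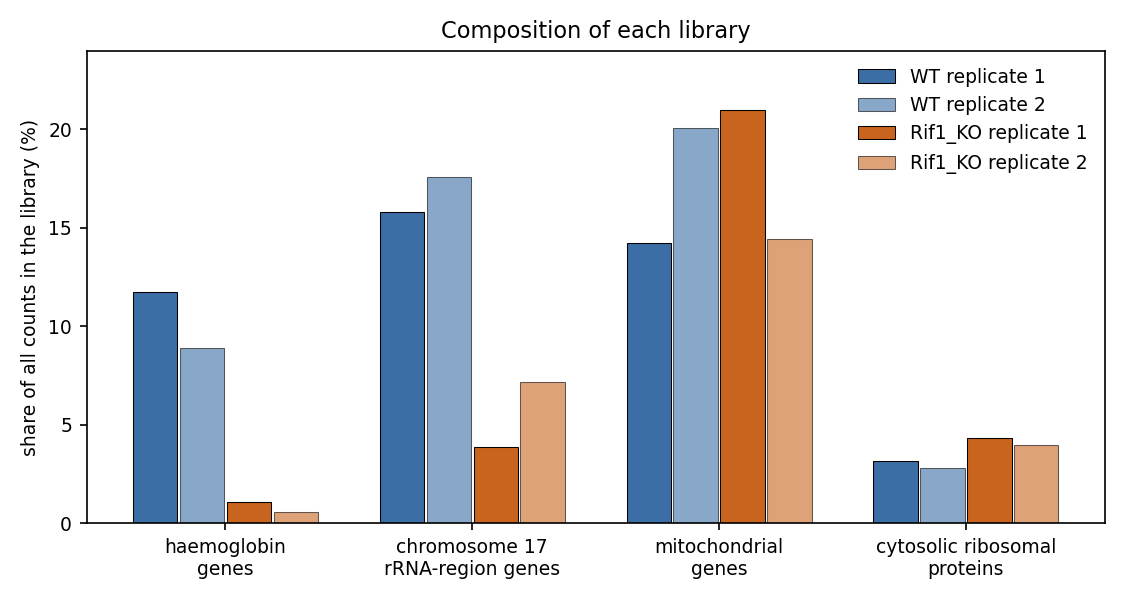
Share of all counts (%) taken by 4 classes of genes, 1 bar per library, with blue bars for libraries labelled WT and orange bars for those labelled Rif1_KO. Haemoglobin genes lie at 11.8% and 8.92% under the label WT and at 1.09% and 0.555% under the label Rif1_KO, while mitochondrial shares overlap between the labels.

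Across 15466 tested genes, 2 genes fell and 0 rose in the libraries labelled Rif1_KO (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05). Both are adult alpha-globin genes on chromosome 11. Hba-a1 (ENSMUSG00000069919.7, 32283511 to 32284465) had 53600 ± 2010 CPM under the label WT and 3230 ± 901 CPM under the label Rif1_KO (SD, n = 2 each). Its log2 fold change was -4.05 (SE 0.30), lower in 2 of 2 libraries, with an edgeR adjusted p of 0.036. Hba-a2 (ENSMUSG00000069917.7, 32296489 to 32297298) had 13700 ± 2340 CPM and 837 ± 208 CPM, a log2 fold change of -4.04 (SE 0.31) and the same edgeR adjusted p. The coding sequences of this pair are near identical, so the split of reads between them is uncertain. At an unadjusted p under 0.05, edgeR gave 1300 genes, 828 with higher and 472 with lower values under the label Rif1_KO; this balance depends on the scaling, with 1055 higher and 295 lower by upper-quartile factors and 783 and 541 by RLE factors (DESeq2's size factors). The counts of called genes moved with the tool and with single libraries. DESeq2 called 521 genes (329 higher, 192 lower) and limma-voom 2. With 1 library left out, the lone library is taken to vary like the pair of the other label. Counts from such fits therefore cannot be set directly beside that of all libraries. Both alpha-globin genes lost their call with upper-quartile factors (edgeR adjusted p = 0.0798), with the stricter filter on low counts (0.175) and with glmTreat against a log2 fold change of 1 (0.0601), and each of these settings called 0 genes.

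No gene rose by this test, and 4 of the 5 genes with the smallest unadjusted p among the higher ones are given as values. Cpa1, which encodes a digestive carboxypeptidase, had 0.0921 and 0.215 CPM under the label WT, from 1 and 2 counts, and 51.2 and 42.7 CPM under the label Rif1_KO. The proteoglycan gene Dcn had 46.8 and 46.0 CPM against 191 and 224 CPM, and the collagen gene Col1a1 46.1 and 87.0 CPM against 385 and 301 CPM. Cstf2, which encodes a factor of mRNA 3' end formation, had 0.737 and 1.83 CPM against 62.5 and 45.1 CPM. The edgeR adjusted p was 0.377 for Cpa1 and 0.571 for the others. DESeq2 called Cpa1 (adjusted p = 8.83e-08) and Cstf2 (2.73e-05) higher, but not Dcn (0.143) or Col1a1 (0.117). Without the filter on low counts edgeR called all 4 higher, with an adjusted p of 0.0114 or less. With each library left out in turn, the log2 fold change was 7.71 to 8.86 for Cpa1 and 2.06 to 2.35 for Dcn. It was 1.98 to 2.9 for Col1a1 and 4.87 to 6.17 for Cstf2. In such fits the lone library is taken to vary like the pair of the other label. Whether a gene passed the threshold there thus depended on which label gave the spread. A rule set before the results picked 57 genes other than Rif1, from each gene list and from the whole table. Of these genes edgeR called 2 with all libraries and DESeq2 22, while DESeq2 called 521 of all 15466 tested genes. The rule takes genes with small p in these same libraries, so a larger share of calls among them is built in.

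Gene lists for the cell types and processes of the embryonic gonad were tested as sets with camera, and 2 of 26 sets were called. Erythroid markers were lower under the label Rif1_KO (adjusted p = 2.69e-12), with a mean log2 difference from the other genes of -4.37. This call was lost with an estimated correlation between genes (camera adjusted p = 0.673). It was also lost with fry, which tests whether the genes of a set move one way on balance (adjusted p = 0.178). An estimated correlation takes its degrees of freedom from the 4 libraries, and with it 0 of 26 sets were called. It gave the same adjusted p of 0.673 to replication genes, whose mean difference was 0.54. Its loss of a call therefore says little about a single list. All 16 tested members had a fitted log2 fold change below 0, with a median of -3.98; 2 members passed the edgeR test over all genes, 12 were lower at an unadjusted p under 0.05, 10 were lower by DESeq2 and 11 adjusted over the list alone. Beside the alpha-globins, 3 members are named here that were chosen after their values were seen. Hba-x and Hbb-y, which encode embryonic globins, differed widely between the libraries labelled Rif1_KO: Hba-x had 30100 and 22900 CPM under the label WT against 2980 and 29.9 CPM, and Hbb-y 32300 and 16800 CPM against 1430 and 49.4 CPM. Alas2, for the erythroid enzyme of haem synthesis, had 254 ± 12.4 CPM against 16.8 ± 5.53 CPM (SD, n = 2 each). Interstitial and stromal markers were higher under the label Rif1_KO as a set (adjusted p = 2.8e-05), with a mean difference of 1.83 and a median of 0.98 over 22 tested members. This call too was lost with an estimated correlation (adjusted p = 0.673) and with fry (0.178). Of these members, 0 passed the edgeR test over all genes, 7 were higher at an unadjusted p under 0.05, 1 was higher by DESeq2 and 4 were higher adjusted over the list alone; 19 had fitted values above 0, among them Dcn and Col1a1. With 1 library left out, 9 of the 26 sets had a mean difference of the opposite sign in at least 1 fit: pluripotency, meiotic, H3K9 and H3K27 methylation, p53 target, BMP, TGF-beta and Nodal, WNT, dissociation stress, endothelial, and mesonephros and epithelium genes. Counting also those whose mean difference changed by more than 1.5 times, 19 sets depended on single libraries; the others were DNA methylation, replication, break repair, apoptosis, stromal, erythroid and X-linked genes.

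**Figure D2:**
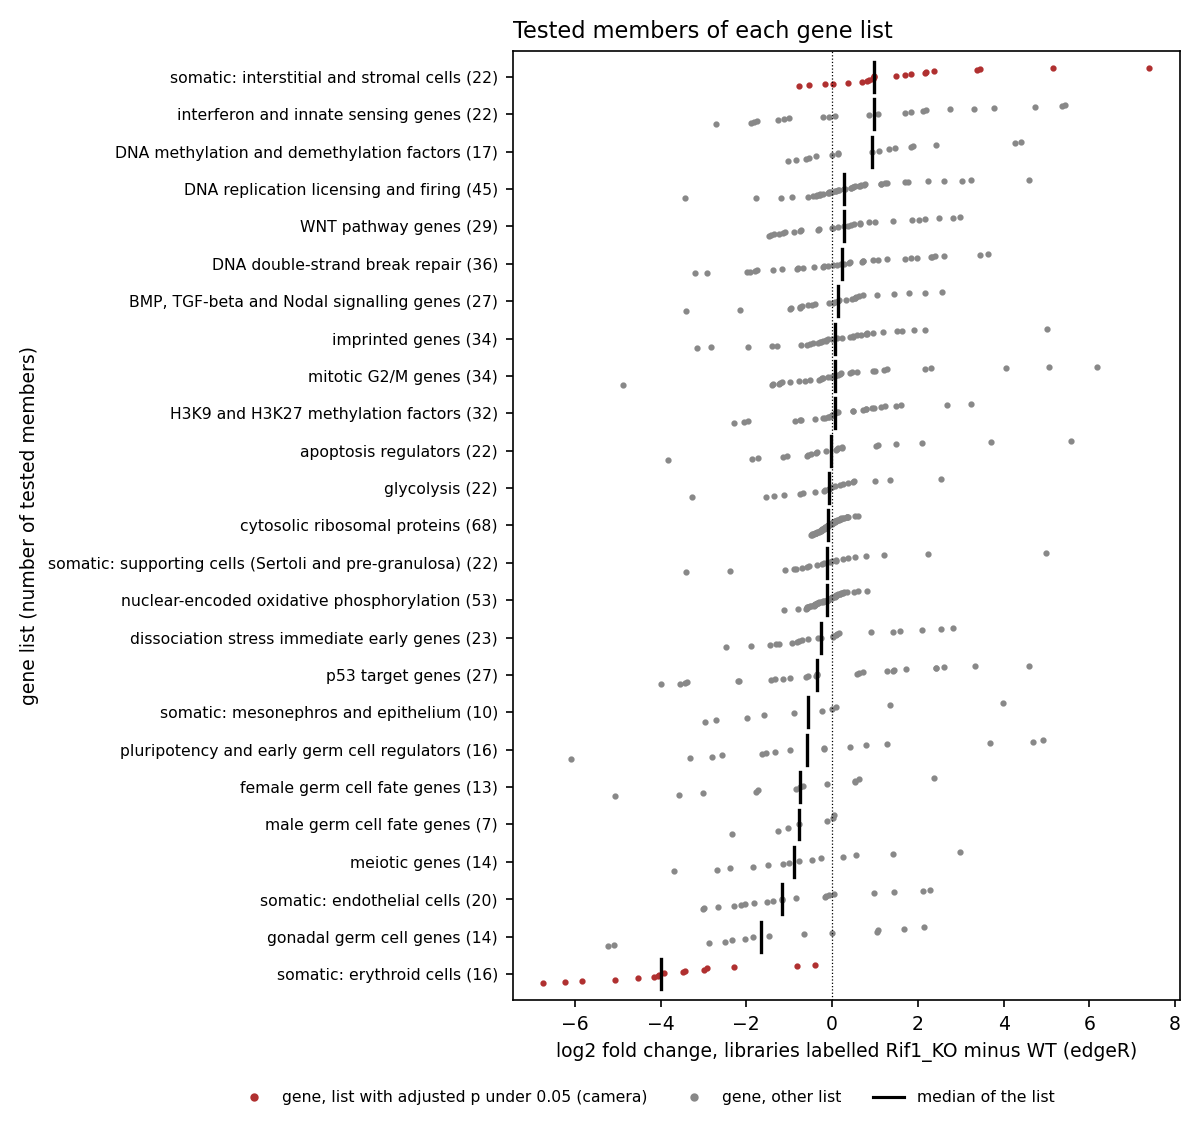
Log2 fold change (Rif1_KO minus WT, by label; edgeR) of each tested member of the gene lists, 1 dot per gene, with a black bar at each list's median and red dots for lists with a camera adjusted p under 0.05. All 16 erythroid members lie below 0 with a median of -3.98, and the stromal median is 0.98.

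Markers of the germ cells themselves were low in most libraries and uneven between replicates. None of the lists of germ cell genes was called by camera on the filtered genes; without the filter on low counts meiotic genes were called lower (adjusted p = 0.0394). Gonadal germ cell genes had a median log2 fold change of -1.66 over 14 tested members and an adjusted p of 0.228; their mean difference from other genes was -1.13, against -1.79 without WT replicate 1 and -0.48 without WT replicate 2. Ddx4, an RNA helicase of germ cells, had 0.645 and 59.2 CPM in the libraries labelled WT and 1.05 and 0.53 CPM in those labelled Rif1_KO. Dazl, an RNA-binding protein required for germ cell development, had 13 and 196 CPM against 2.03 and 4.08 CPM. The mean under the label WT thus rests on WT replicate 2 for both genes. Without WT replicate 2 the log2 fold change was 0.28 for Ddx4 and -2.08 for Dazl, and without WT replicate 1 it was -6.22 and -5.99. It was -5.7 and -4.58 without Rif1_KO replicate 1, and -4.78 and -5.64 without Rif1_KO replicate 2. DESeq2 called both lower (adjusted p of 0.0231 for Ddx4 and 0.0031 for Dazl). For pluripotency and early germ cell regulators the median was -0.59 (16 tested, adjusted p = 0.723), and the mean difference from other genes was -0.36, against -1.27 without WT replicate 1 and 0.56 without WT replicate 2. Prdm14, a transcriptional regulator of early germ cells, had 19.9 and 18.4 CPM against 0.452 and 0.106 CPM. Its edgeR adjusted p was 0.571, and its log2 fold change was -7.3 to -5.35 with 1 library left out. Tcl1 had 0.368 and 0.752 CPM against 7.84 and 21.5 CPM. DESeq2 called Prdm14 lower (adjusted p = 4.08e-05) and Tcl1 higher (adjusted p = 0.00651). Meiotic genes (median -0.88, 14 tested, adjusted p = 0.396) included Syce1, with 3.41 and 6.45 CPM against 0.151 and 0.583 CPM, and Ythdc2, with 1.11 and 1.5 CPM against 4.37 and 16.3 CPM; their mean difference was -0.65, against -1.42 without WT replicate 1 and 0.1 without WT replicate 2. Male germ cell fate genes had a median of -0.78 (7 tested, adjusted p = 0.228) and female germ cell fate genes one of -0.74 (13 tested, adjusted p = 0.636). The mean difference of the female list was -0.77, against -1.43 without WT replicate 1, -0.12 without WT replicate 2, -1.25 without Rif1_KO replicate 1 and -0.29 without Rif1_KO replicate 2. In these lists Piwil4 had 1.47 and 2.36 CPM against 0.603 and 0.159 CPM, Fgfr3 1.84 and 2.15 CPM against 0.904 and 0.742 CPM, Msx1 78.5 and 27.4 CPM against 13.3 and 18.6 CPM, and Rhox9 0.276 and 113 CPM against 3.39 and 0.053 CPM. Only 4 two-cell stage genes were tested, too few for camera. Among them Zfp420 had 0.921 and 1.61 CPM against 1.28 and 25.4 CPM, and Duxf3 3.59 and 4.62 CPM against 3.47 and 1.32 CPM. Some germ cell values under the label Rif1_KO rest on few counts, with 6 and 2 for Prdm14, 2 and 11 for Syce1 and 45 and 1 for Rhox9.

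**Figure D3:**
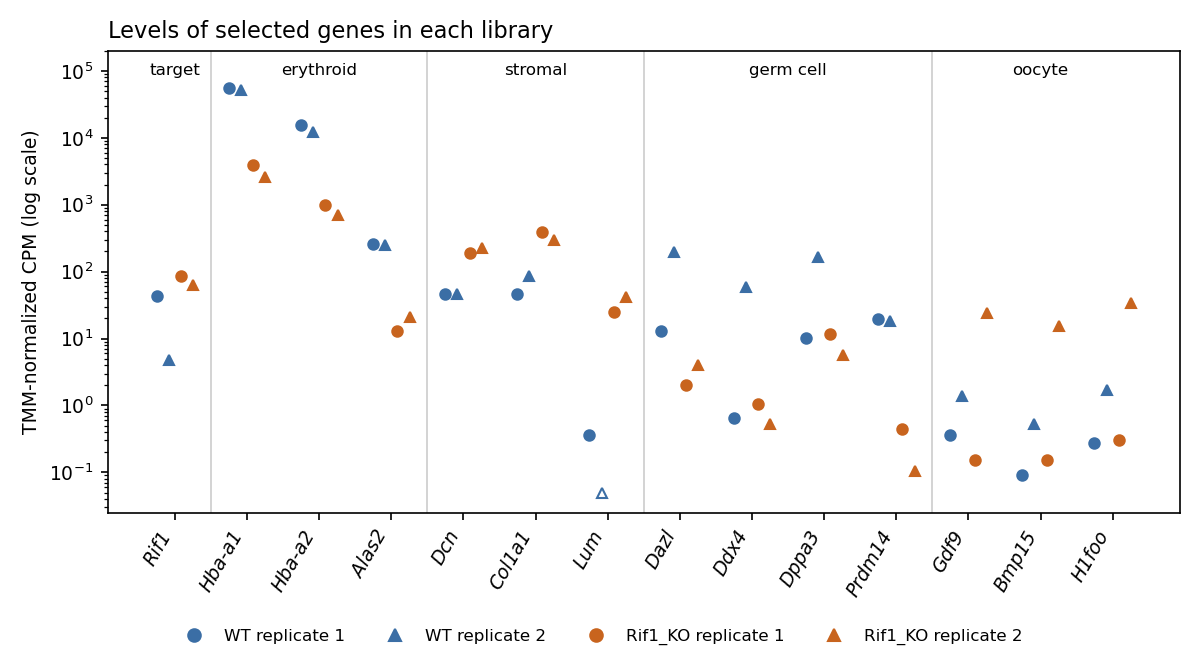
TMM-normalized CPM (log axis) of 14 genes in each library, with blue symbols for libraries labelled WT, orange for Rif1_KO, circles for replicate 1 and triangles for replicate 2; a value of 0 is drawn as an open symbol at 0.05 CPM. The oocyte genes, Alas2, Lum and Dppa3 were chosen after their values were seen; Dazl and Ddx4 are highest in WT replicate 2 (196 and 59.2 CPM) and Gdf9 is highest in Rif1_KO replicate 2 (23.7 CPM).

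Among lists for replication, repair and chromatin, where Rif1 is known to act, and for interferon genes, none was called by camera on the filtered genes and 0 members passed the edgeR test over all genes. Without the filter on low counts camera called all 5 of these lists higher under the label Rif1_KO. Its adjusted p was 0.000836 for replication, 0.00196 for break repair, 0.0065 for DNA methylation, 0.00703 for H3K9 and H3K27 methylation and 0.00667 for interferon genes. In that setting 45215 genes were tested, so each list was compared with many more genes. The mean difference from other genes rose in all sets tested both ways but the meiotic and X-linked genes. For ribosomal proteins it went from -0.3 to 0.11. These calls therefore cannot be told from a change in the genes compared. DNA replication licensing and firing genes had a median log2 fold change of 0.29 (45 tested, adjusted p = 0.228), with 2 members higher and 0 lower at an unadjusted p under 0.05 and 1 higher and 1 lower by DESeq2. Orc6, a subunit of the origin recognition complex, had 14.6 and 20.2 CPM under the label WT and 121 and 92.8 CPM under the label Rif1_KO. Its edgeR adjusted p was 0.571, and its log2 fold change was 2.4 to 2.87 with 1 library left out. The licensing factor Cdc6 had 0.368 and 0.967 CPM against 16.4 and 16.2 CPM. DNA double-strand break repair genes had a median of 0.24 (36 tested, adjusted p = 0.228), with 2 members higher at an unadjusted p under 0.05 and 0 by DESeq2. In that list Rad52 was at 0.461 and 0.645 CPM against 7.01 and 6.99 CPM, and Nhej1 at 0.645 and 0.322 CPM against 4.37 and 6.36 CPM. DNA methylation and demethylation factors had a median of 0.94 (17 tested, adjusted p = 0.228), with 2 members higher at an unadjusted p under 0.05 and 2 by DESeq2. The de novo methyltransferase gene Dnmt3b had 0.461 and 1.07 CPM against 21.6 and 11.3 CPM, and Uhrf2 0.829 and 3.87 CPM against 51.7 and 38.9 CPM. H3K9 and H3K27 methylation factors had a median of 0.06 (32 tested, adjusted p = 0.495), with Kdm4a at 2.40 and 4.41 CPM against 0.753 and 0.636 CPM and Kdm4c at 0.368 and 2.58 CPM against 10.2 and 17.6 CPM. Interferon and innate sensing genes had a median of 0.97 (22 tested, adjusted p = 0.228), with 4 members higher at an unadjusted p under 0.05 and 2 by DESeq2. Their mean difference was 0.76, against 1.34 without WT replicate 1 (adjusted p = 0.0824) and 0.18 without WT replicate 2 (adjusted p = 0.913). Stat2 was at 0.0921 and 0.215 CPM against 6.40 and 7.52 CPM and Ifit3 at 0.0921 and 0 CPM against 3.92 and 0.847 CPM. Under the label WT these came from 1 and 2 counts for Stat2 and 1 and 0 counts for Ifit3, below the floor of 3 counts.

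Lists of cell cycle, stress, imprinted, signalling and metabolic genes were not called by camera on the filtered genes, and 0 of their members passed the edgeR test over all genes. Without the filter on low counts camera called 3 of them higher, with an adjusted p of 0.00458 for mitotic, 0.0245 for imprinted and 0.0119 for WNT pathway genes. As given above, that setting raised the mean difference of nearly all sets. DESeq2 called 3 mitotic genes higher and 1 lower, 1 p53 target higher and 2 lower, 1 apoptosis regulator higher and 1 lower, 1 imprinted gene higher and 1 BMP, TGF-beta or Nodal gene lower. Mitotic G2/M genes had a median of 0.06 (34 tested, camera adjusted p = 0.228). The mitotic kinase gene Aurkb was at 0.0921 and 0.43 CPM (1 and 4 counts) against 15.7 and 23.1 CPM. Another, Bub1, was at 0.184 and 1.5 CPM (2 and 14 counts) against 27.4 and 28.7 CPM. The p53 target genes had a median of -0.36 (27 tested, adjusted p = 0.844), with Trp53inp1 at 36.9 and 104 CPM against 8.44 and 3.60 CPM and Ccng1 at 0.276 and 1.61 CPM against 34.5 and 11.7 CPM. Apoptosis regulators had a median of -0.03, with a camera direction of higher (22 tested, adjusted p = 0.636); Casp8 had 0.461 and 0.537 CPM against 10.5 and 37.3 CPM, and Bcl2l1 91.0 and 19.8 CPM against 2.03 and 5.72 CPM. Immediate early genes of tissue dissociation had a median of -0.25 (23 tested, adjusted p = 0.777), with camera and the mean log2 fold change of -0.04 pointing lower while the mean difference from other genes was 0.05; Dusp1 had 87.2 and 231 CPM against 28.0 and 57.4 CPM, and Myc 85.3 and 150 CPM against 44.0 and 55.4 CPM. Imprinted genes had a median of 0.06 (34 tested, camera adjusted p = 0.616), and 1 of them, Dcn, was higher adjusted over the list alone. Airn had 0.0921 and 0.322 CPM (1 and 3 counts) against 5.65 and 8.10 CPM. In BMP, TGF-beta and Nodal signalling the median was 0.14, with a camera direction of lower (27 tested, adjusted p = 0.826), and Smad4 had 12.6 and 6.34 CPM against 57.9 and 53.9 CPM. WNT pathway genes had a median of 0.28 (29 tested, adjusted p = 0.489), with Lgr4 at 645 and 519 CPM against 1560 and 780 CPM. Glycolysis genes had a median of -0.06 (22 tested, adjusted p = 0.779), with Aldoa at 703 and 622 CPM against 304 and 491 CPM and Slc2a1 at 72.0 and 40 CPM against 12.7 and 25.6 CPM. Nuclear-encoded oxidative phosphorylation genes had a median of -0.12 (53 tested, adjusted p = 0.266), with Sdha at 127 and 185 CPM against 82.7 and 61.4 CPM and Ndufb10 at 113 and 107 CPM against 195 and 190 CPM. Cytosolic ribosomal protein genes had a median of -0.09 (68 tested, adjusted p = 0.396), with Rpsa at 321 and 287 CPM against 473 and 408 CPM and Rpl21 at 147 and 158 CPM against 246 and 219 CPM.

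Markers of other gonadal cells were read in the same way. Wt1, a transcription factor of gonadal somatic cells and chosen after its values were seen, had 227 and 95.7 CPM under the label WT and 155 and 168 CPM under the label Rif1_KO. Supporting cell genes (Sertoli and pre-granulosa) had a median log2 fold change of -0.12 (22 tested, adjusted p = 0.785). In that list Inhbb, a subunit of inhibin and activin, had 23.5 and 39.4 CPM against 2.19 and 3.71 CPM. Aard had 0.0921 and 0.43 CPM (1 and 4 counts) against 14.8 and 2.17 CPM. DESeq2 called Inhbb lower (adjusted p = 0.0114) and Aard higher (adjusted p = 0.0373). Endothelial genes had a median of -1.17 (20 tested, adjusted p = 0.228), with the junction gene Cldn5 at 76.1 and 48.8 CPM against 0.603 and 15.1 CPM and Eng at 55.4 and 10.2 CPM against 1.66 and 6.51 CPM. This list was called lower without WT replicate 2 (adjusted p = 0.00406) and without Rif1_KO replicate 2 (adjusted p = 0.0272), and its mean difference without WT replicate 1 was 0.18. Mesonephros and epithelium genes had a median of -0.56 (10 tested, adjusted p = 0.489), with the keratin gene Krt8 at 84.4 and 103 CPM against 10.5 and 37.0 CPM and Epcam at 20.4 and 61.3 CPM against 3.24 and 9.27 CPM. The mean difference of this list was -0.48, against -1.54 without WT replicate 1 and 0.58 without WT replicate 2. Only 3 macrophage and leukocyte genes were tested, too few for camera; Ptprc had 1.11 and 1.61 CPM against 0.452 and 0.265 CPM, and Csf1r 0.645 and 16.9 CPM against 1.13 and 2.81 CPM.

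The sex of the embryos is not in the labels, and genes of the sex chromosomes were read for differences between libraries. Xist, the RNA of the inactive X chromosome, had 142 and 135 CPM in the libraries labelled WT and 37.5 and 98.3 CPM in those labelled Rif1_KO (log2 fold change -1.03, edgeR adjusted p = 0.668). Of 10 Y-linked genes, Eif2s3y had 3 counts and Ddx3y 1 count in WT replicate 2, and 0 counts of any of them were found in the other libraries. A count of 0 allows up to 0.235 CPM in WT replicate 1, and 0.249 and 0.208 CPM in the libraries labelled Rif1_KO. Xist was thus present in every library while Y-linked transcripts were almost absent, which argues against a large share of male cells in any of them. The 532 tested X-linked genes were not called as a set: camera gave a direction of higher with an adjusted p of 0.475, the mean log2 fold change was 0.25 and the median -0.02. Of these genes 0 passed the edgeR test over all genes, 42 were higher and 13 lower at an unadjusted p under 0.05, DESeq2 called 27 higher and 7 lower, and 1 was lower adjusted over the list alone.

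The replicates of each label were unequally alike. Across 15466 genes, which are not independent replicates, Pearson's r of log2 CPM was 0.823 between the libraries labelled Rif1_KO and 0.637 between those labelled WT, below the 0.672 to 0.718 between libraries of different labels. Between the libraries labelled WT, 695 genes had at least 20 CPM in one and at most 1 CPM in the other. That number was 24 between the libraries labelled Rif1_KO and 245 to 354 between libraries of different labels.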

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

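The fit without haemoglobin, mitochondrial and rRNA-region genes was chosen after the results were seen; the other settings were planned. Against 2 called genes (0 higher and 2 lower under the label Rif1_KO), DESeq2 called 521 (329 higher, 192 lower), edgeR without a filter on low counts 54 (18 higher, 36 lower), and edgeR with upper-quartile factors, with the stricter filter, and with glmTreat 0 each. These differences have causes that were not tested, except that DESeq2 made 133 false calls in the simulation. Leaving out 1 library gave 5 to 871 called genes (0 to 487 higher, 5 to 384 lower): 871 without WT replicate 1, 545 without WT replicate 2, 5 without Rif1_KO replicate 1 and 6 without Rif1_KO replicate 2, where the lone library is taken to vary like the other group. Both alpha-globin genes were among the calls each time. The fit without haemoglobin, mitochondrial and rRNA-region genes called 0 genes, because it leaves out both called genes. limma-voom, DESeq2 size factors in edgeR, no robust dispersion and no X and Y genes each called 2 genes, both shared with the main test. Hba-a1 had an edgeR adjusted p of 0.0798 with upper-quartile factors, 0.175 with the stricter filter and 0.0601 with glmTreat, with log2 fold changes of -3.77, -4.07 and -4.05, and Hba-a2 had the same adjusted p values with -3.75, -4.05 and -4.04.

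The log2 fold change of Rif1 was above 0 in every alternative run. It ranged from 0.78 without WT replicate 2 to 3.99 without WT replicate 1, and passed the threshold in the latter only (adjusted p = 0.00248, against 0.515 to 1 in the other alternatives). With an estimated correlation and with fry, 0 lists were called against 2 with camera: the mean differences of 1.83 for stromal and -4.37 for erythroid markers stay as they are and their adjusted p values become 0.673 and 0.178. Without a filter on low counts 11 lists were called. Beside stromal and erythroid markers, the lists for replication, break repair, DNA methylation, H3K9 and H3K27 methylation, mitotic, interferon, imprinted and WNT pathway genes were higher and meiotic genes lower. The mean difference rose there in all sets tested both ways but the meiotic and X-linked genes. The added calls of higher lists therefore cannot be told from a change in the genes compared, and no other cause was tested. Stromal and erythroid markers kept their call in the other alternatives, and with 1 library left out the mean difference was 1.39 to 2.29 for stromal and -5.16 to -3.55 for erythroid markers. X-linked genes were not called in any alternative. Of 806 alternative values for 57 named genes other than Rif1, 3 had the opposite sign. Of 284 alternative values for the lists 22 had the opposite direction, and none of these genes or lists was past the threshold in both settings. Of these 57 genes edgeR called 2 in the main test and DESeq2 22. The genes were picked by small p in these same libraries, so their agreement in sign was in large part built in. With a total that leaves out mitochondrial genes the mean haemoglobin share under the label WT was 12.4% against 10.3%.

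With the replicate number as a block (the replicate block), edgeR called 7 genes, 0 higher and 7 lower, against 2. The correlation of deviations from the group means between libraries of the same number was -0.023 across genes, and no label says that the numbers mark a shared litter or day, so the numbers were not taken to pair the libraries.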

Other observations

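All tests in this part were chosen after the results were seen. Transcripts of growing oocytes and eggs, a list of 42 genes collected after their values were seen, were found mainly in 1 library. In Rif1_KO replicate 2, 20 of them reached 5 CPM or more, against 2 in Rif1_KO replicate 1, 1 in WT replicate 1 and 0 in WT replicate 2. H1foo, the oocyte linker histone, had 34.4 CPM in Rif1_KO replicate 2 and 0.301, 0.276 and 1.72 CPM in Rif1_KO replicate 1, WT replicate 1 and WT replicate 2. The oocyte growth factor genes Gdf9 and Bmp15 had 23.7 and 15.3 CPM in Rif1_KO replicate 2 and at most 1.40 CPM elsewhere. Several germ cell transcripts were highest in WT replicate 2: Dppa3 had 165 CPM there and 10.2, 11.8 and 5.77 CPM in WT replicate 1, Rif1_KO replicate 1 and Rif1_KO replicate 2, and the meiotic gene Stra8 26.2 CPM against at most 0.553 CPM. Pou5f1, a transcription factor of primordial germ cells, had at most 1.20 CPM in every library.

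Erythroid transcripts were lower in both libraries labelled Rif1_KO. With haemoglobin, mitochondrial and rRNA-region genes left out before the totals, the 9 other tested erythroid genes kept a median log2 fold change of -3.42 (quartiles -5.77 and -2.24). The median of all tested genes went from -0.111 to -0.061 in that fit, and it was 0.164 with upper-quartile factors. A scaling shift is shared by all genes, and the 9 genes lay far below the median of all in both fits. These values argue against scaling by the few genes that take many counts as the source of the fall in these 9 genes. In the main fit these 9 genes had a median of -3.47 (quartiles -5.82 and -2.28) with 9 of 9 below 0. The fall was therefore not confined to haemoglobin genes. A smaller amount of erythroid cells or their RNA in the sorted material is a candidate explanation. The 9 genes are no separate support for it, since they belong to the 16 list members already seen to lie below 0. Of the erythroid list 0 genes are in another list, but the lists were chosen by hand, so this does not show that only erythroid cells express them. How far the enrichment removed erythroid cells cannot be judged, since its marker and the purity are not given. The most abundant genes of the list in the libraries labelled WT are Hba-a1, Hba-x and Hbb-y. In Rif1_KO replicate 2, Hba-a2 (690 CPM) lay above Hba-x and Hbb-y. Without Rif1_KO replicate 1 the log2 fold change was -9.71 for Hba-x, -8.88 for Hbb-y and -4.29 for Hba-a1. Without Rif1_KO replicate 2 it was -3.14 for Hba-x and -3.78 for Hba-a1. A smaller amount of the same RNA would lower these genes alike, so amount alone does not describe Rif1_KO replicate 2. Whether the genotype or the enrichment of each sample set the amount or the kind of erythroid RNA was not tested and stays open.

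Rif1 transcript was higher in both libraries labelled Rif1_KO. Of 1986 genes within 0.58 of its mean level on the log2 scale, 8.36% had a log2 fold change at least as large in size. These fold changes come from the same comparison of labels. They therefore cannot tell the spread between libraries made from few cells from a difference between the labels. Reads from exons outside a deleted part were not tested, since 1 count per gene does not say which exons the reads come from. The lowest level under the label Rif1_KO was 1.46 times the highest under the label WT, an order that exchanged labels would also give, and no other value here checks the genotype, so that this stays open.

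Germ line transcripts stood out in single libraries. A larger share of germ cells in WT replicate 2 and uneven capture from few cells cannot be told apart: 20 of 44 tested members of the 3 germ cell, meiotic and pluripotency lists (45.5%) were highest there against 29.6% of all tested genes, with a two-sided Fisher exact p of 0.03 over genes that are not independent. Oocyte or egg RNA in Rif1_KO replicate 2, which includes carry-over from another library that a count table cannot check, also stays open, since Zp1, Zp2 and Zp3, abundant in growing oocytes, had a median of 1.22 CPM there while the other list members had one of 5.51 CPM, and the list was collected from what was seen. No biological explanation by genotype was tested for the values that stand out in 1 library, since the labels do not set that library apart.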
